A study of Mus musculus with 2 samples.

How the data were processed

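Fixed RNA profiling of the liver, a probe-based single-cell assay of 10x Genomics in which 4 livers are pooled and told apart by probe barcodes, was run on 25 mg of snap-frozen liver from each of 8 male mice in 2 pools, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and cell, not normalized, made with Cell Ranger 7.0.0 per the file headers, and mm10 is named in the submitters' processing notes. Further cell filters before deposit are not stated. The other deposited files are text (barcode lists, lists of gene identifiers and symbols, and the authors' key), and the key gives each liver's probe barcode, genotype, treatment and time. For the ChATflox 24 h liver the barcode list is a copy of the list of the ChATflox;Mb1-Cre 24 h liver, with 11057 lines for 10240 columns, so it was not used. The library labelled ChATflox;Mb1-Cre sham has no barcode list among the files used. The livers are separate matrices, so the values could be read without these lists, but the barcodes of these 2 livers could not be checked against the key. That the matrix of the ChATflox 24 h liver is the right one, on which all its values at 24 h rest, was therefore not checked either. All other conditions were taken from the key as given.

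Of 80497 deposited cells, 80489 with at least 500 UMIs were kept. Doublets were scored within each liver against simulated doublets (expected rate 0.08), and 7.32% to 9.87% of the cells of each liver were called doublets. They stayed in for clustering and were left out of the sums and shares. Clustering ran on Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Its steps were scaling to 10000 UMIs per cell, log transformation, 2000 variable genes (scanpy 1.11.5), 40 principal components and a graph of 15 neighbours weighted by shared neighbours. Leiden clustering of igraph 0.11.9 at a resolution of 1.0 gave 55 clusters. No batch correction was applied. Each cluster was named by the best of 17 lists of cell type markers, with at least 3 markers raised, and clusters with over 40% doublets were left out. Between 0.979% and 5.43% of the cells of each liver stayed unnamed. The names end in "-like" because they rest on markers alone. Classes with at least 20 cells in every liver were tested, hepatocyte-like cells and 10 others. Dendritic, mesothelial and plasma cell-like cells fell short, with 18, 1 and 3 cells in their smallest liver.

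UMI counts were summed per liver and class. edgeR 4.0.16 on R 4.3.3 fitted time (4 levels) and genotype additively with TMM scaling, filterByExpr and the quasi-likelihood F test, over all 8 livers, leaving 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes of a class, and a gene is called at an adjusted p under 0.05. A count before adjustment is the number of genes with an unadjusted p under 0.05. Genes tested numbered 12981 in hepatocyte-like cells, 3735 to 11412 in the other classes and 14151 in the sum of all cells. CPM are class sums scaled to their plain totals, without TMM factors, and ± is the SD between livers. The log2 changes and ratios fitted by edgeR include these factors, so they can differ from the ratio of the CPM beside them. In hepatocyte-like cells the factors ran from 0.750 (ChATflox 4 h) to 1.37 (ChATflox;Mb1-Cre 24 h). The hepatocyte genes that the naming rule picked within single times are the exception, with ratios and CPM on TMM-adjusted totals. Time comparisons share the sham livers, so no overlap between them is claimed. Because 2 h and 4 h livers form a pool of their own, pool cannot be estimated beside time, and genotype is balanced within pools. The 28 gene lists of liver and immune pathways were tested with camera of limma 3.58.1 (preset correlation 0.01, and estimated), and with fry, on log2 CPM with a prior count of 2. List p-values were adjusted over the lists of a comparison. Counts adjusted over the list alone re-adjust the gene p-values within the list.

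Shares of cells have exact Clopper-Pearson 95% intervals, UMI counts exact Poisson intervals, and a count of 0 allows 3 counts of the total per liver. Intervals and floors cover counting error only. Genotype differences in shares and in Cd79a were tested with two-sided exact sign-flip permutation tests over the 4 times (16 sign patterns). Genotype ratios at 1 time compare 1 liver with 1 liver and have counting intervals only. For cycling cells, hepatocyte-like cells with at least 2000 UMIs were thinned to 2000, and the 134 to 344 cells per liver below that were left out. The depth ranges from 101229508 to 349558878 UMIs per liver, and the B cell-like class holds 22 to 387 cells per liver. Counts were simulated from the gene means and library sizes of the real livers, with 1 dispersion for all genes and no other difference between livers. In them edgeR recovered 5% of 2-fold and 44% of 4-fold changes of hepatocyte-like cells at 24 h against sham, over 12981 genes. For the genotype it recovered 18% and 96% over the same genes. The real livers also differ in ways not simulated, so these shares may overstate the recovery in them.

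The comparisons, lists, markers, tests, most alternatives and the rule for named genes were chosen before the data were examined. The rule names, for hepatocyte-like cells, the 10 called genes with the largest rise and the 10 with the largest fall that have at least 20 CPM on one side and the same direction in both genotypes (at all 4 times for genotype). Other classes give 3 each way, every list up to 4 members, and a comparison with no call its 3 smallest p. For 1 liver against 1, the rule names up to 5 genes each way with at least 50 UMIs. Only some of the genes so named are printed. Gene positions are from GENCODE annotation of the mm10 build. The alternatives were DESeq2 1.42.0, no count filter, each liver left out, no genotype term, no time term, livers after PHX only, a minimum of 1000 UMIs per cell, doublets kept, a resolution of 2.0 (77 clusters), and cells thinned to at most 2000 UMIs before summing. Hepatocyte-like cells with under 1% mitochondrial UMIs alone or the others alone, the genotype effect at 4 h and 24 h only, the comparison of 4 h with 2 h, and shares of cells with the 2 sham labels exchanged were added after the data were seen. Figures were drawn with matplotlib 3.10.9.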

Results

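Partial hepatectomy (PHX), the removal of most of the liver, makes the remaining hepatocytes, the liver's metabolic cells, leave their resting state and rebuild the organ. The study asks whether acetylcholine made by B lymphocytes controls this regeneration. Chat encodes choline acetyltransferase, the enzyme that makes acetylcholine. ChATflox mice carry a Chat gene that Cre recombinase can delete, and ChATflox;Mb1-Cre mice also carry a Cre driven by Mb1, another name for the B cell gene Cd79a. Snap-frozen liver of 8 male mice was profiled cell by cell with fixed RNA profiling, an assay that counts probe pairs bound to RNA as unique molecular identifiers (UMIs). There was 1 ChATflox and 1 ChATflox;Mb1-Cre mouse after sham surgery and at 2 h, 4 h and 24 h after PHX, so each time has 2 livers and each genotype at a given time has 1. The sham livers were taken 24 h after surgery, so the 2 h and 4 h livers have no sham liver of their own time. The 2 h and 4 h livers shared 1 pool and the 24 h and sham livers the other. The livers held 8408 to 12985 deposited cells with median depths of 2872 to 6610.5 UMIs per cell and totals of 101229508 to 349558878 UMIs. Hepatocyte-like cells made up 43.6% to 53% of the cells in each liver, and sinusoidal endothelial, Kupffer and stellate cells were the next most abundant classes.

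The genotype was first looked for in the B cells themselves. Chat, on chromosome 14 (32408203 to 32465989, mm10), gave 0 UMIs in the B cell-like cells of 7 livers. In the library labelled ChATflox;Mb1-Cre sham it gave 4 UMIs in 4 of 387 cells, a share of 1.03% and a level of 5.71 CPM (95% interval 1.56 to 14.6). The T cell-like cells, which serve as a background, gave 0 Chat UMIs in all livers, the hepatocyte-like cells at most 1 UMI per liver, and all cells together 1 to 8 UMIs per liver. With 22 to 387 B cell-like cells per liver, a count of 0 allows up to 6.64 CPM in the library labelled ChATflox sham and up to 29.3 CPM in the ChATflox;Mb1-Cre 4 h liver, so a loss of Chat was not detectable at this depth. The Mb1-Cre allele sits in Cd79a itself, which encodes a signalling chain of the B cell receptor, and Cd79b, its partner chain on chromosome 11, serves as the reference. In B cell-like cells, Cd79a gave 0.559 (0.397 to 0.780) UMIs per Cd79b UMI in the ChATflox;Mb1-Cre liver at 2 h, 0.443 (0.289 to 0.668) at 4 h and 0.542 (0.426 to 0.687) at 24 h. The ChATflox livers gave 1.12 (0.857 to 1.47), 1.5 (1.18 to 1.91) and 1.65 (1.27 to 2.15) at the same times. The sham pair ran the other way, with 1.45 (1.30 to 1.62) in the library labelled ChATflox;Mb1-Cre sham and 0.691 (0.595 to 0.801) in the library labelled ChATflox sham. Over the 4 pairs the mean log2 ratio of ChATflox;Mb1-Cre to ChATflox was −0.82 (SD 1.31), lower in 3 of 4, with p = 0.375 by an exact sign-flip test whose smallest possible p is 0.125. Against the other B cell markers together the ratio of ChATflox;Mb1-Cre to ChATflox was 1.83 in the sham pair, 0.482 at 2 h, 0.330 at 4 h and 0.507 (0.385 to 0.667) at 24 h. Against Cd79b it was 0.329 at 24 h, where Cd79b itself stood at 1.74 (1.32 to 2.31) times its ChATflox level relative to the rest of those markers. Cd79a UMIs were found in 53.4% to 91.1% of B cell-like cells, with medians of 944 to 2511.5 UMIs per cell. They were found in 0.110% to 0.672% of hepatocyte-like cells, with medians of 7525 to 20932.5. Where the probes lie relative to the deleted part of Chat or the inserted Cre is not given, so neither gene checks the deletion, and every genotype direction that follows takes the sham pair as labelled, against its Cd79a ratio.

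**Figure D1:**
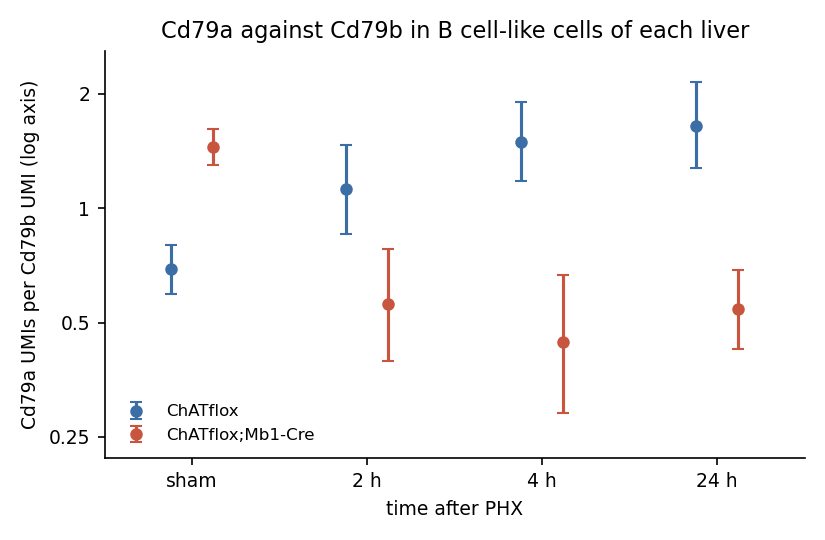
Cd79a UMIs per Cd79b UMI (log axis) in the B cell-like cells of each liver against time after PHX, with 95% counting intervals as bars. The ChATflox;Mb1-Cre livers lie at 0.443 to 0.559 after PHX, while the library labelled ChATflox;Mb1-Cre sham lies at 1.45, above the library labelled ChATflox sham at 0.691.

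By 2 h after PHX 65 genes had risen in hepatocyte-like cells and 4 had fallen. The metallothioneins Mt2 and Mt1, small proteins that bind zinc and copper, rose the most. Mt2 (chromosome 8, 94172664 to 94173568) went from 3.29 ± 0.302 to 6166 ± 387 CPM (SD, n = 2), a log2 change of 11.15 (SE 0.99, adjusted p = 0.0357), and Mt1 beside it changed by 9.22 (SE 1.05, adjusted p = 0.0367). Lcn2, a secreted protein that withholds iron from bacteria, went from 4.70 ± 0.679 to 663 ± 226 CPM (log2 change 7.48, SE 0.62, adjusted p = 0.0343). The serum amyloid genes Saa2 and Saa1 rose by 7.26 and 5.84 on the log2 scale, the neutrophil chemokine Cxcl1 by 7.14, the metalloreductase Steap4 by 4.86, and Syt12, Dusp8 and Arid5a by 6.91, 5.62 and 4.92. Among 22 immediate early genes, which cells switch on within minutes of a stimulus, 4 rose, and 20 when adjusted over the list alone (median log2 change 4.32, camera adjusted p = 2.5e-15, and adjusted p = 0.295 with an estimated correlation). They include Junb, an AP-1 subunit, which went from 18.6 ± 12.2 to 303 ± 45.3 CPM (log2 change 4.49, SE 0.45, adjusted p = 0.0367), and Klf10, Dusp1 and Zfp36, at 3.34, 2.93 and 2.74. Of 26 acute phase genes 6 rose, and 19 when adjusted over the list alone (median 1.80, camera adjusted p = 6.0e-16, and adjusted p = 0.235 with an estimated correlation), among them Socs3, the brake on IL-6 signalling, at 3.89 and the transcription factor Cebpd at 3.15. Of 12 genes of gluconeogenesis and the fasting response 1 rose, and 9 when adjusted over the list alone (median 1.73, camera adjusted p = 4.5e-06, and adjusted p = 0.235 with an estimated correlation). Sds and Got1, enzymes of amino acid catabolism, rose by 2.35 and 2.42, and Lpin1, a phosphatase of lipid synthesis, by 4.28. Of the few genes that fell, Arrdc3, an arrestin-like adaptor, went from 85.4 to 7.97 CPM (log2 change −3.10, SE 0.36, adjusted p = 0.0367), Gse1 changed by −1.73 and the Wnt receptor gene Fzd4 by −1.58. Of 12981 genes tested, edgeR called 65 higher and 4 lower (69 in all, 2264 before adjustment), and DESeq2 called 1195. This comparison is also one between pools, and without ChATflox sham, ChATflox;Mb1-Cre sham, ChATflox 4 h or ChATflox;Mb1-Cre 4 h, as labelled, edgeR called 0 genes (1418, 744, 2038 and 2038 before adjustment). It called 2 without ChATflox 2 h, 411 without ChATflox 24 h and 290 without ChATflox;Mb1-Cre 24 h.

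At 4 h hepatocyte-like cells had 362 genes called higher than sham and 351 called lower. Cdkn1a, the inhibitor of cyclin-dependent kinases also called p21 (chromosome 17, 29090976 to 29100727), went from 17.2 ± 5.84 to 397 ± 46.1 CPM (SD, n = 2), a log2 change of 5.03 (SE 0.63, adjusted p = 0.0207). It was the member that rose of 14 p53 targets and kinase inhibitors, a list with a median of 0.17 (1 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.873, and adjusted p = 0.934 with an estimated correlation). Of 24 genes of the G1/S step and DNA replication 1 rose and 4 fell, the same counts as when adjusted over the list alone (median −0.71, camera adjusted p = 0.00210, and adjusted p = 0.269 with an estimated correlation). Mcm10, a replication initiation factor, went from 55.0 to 7.47 CPM (log2 change −2.40, SE 0.39, adjusted p = 0.0318), and Cdt1, which licenses origins, changed by −2.33. Of 26 acute phase genes 16 rose, and 22 when adjusted over the list alone (median 2.50, camera adjusted p = 1.2e-14, and adjusted p = 0.269 with an estimated correlation). Lcn2, Saa2 and Saa1 stood 9.39, 8.80 and 7.21 above sham on the log2 scale, Stat3, the transcription factor behind IL-6, 2.10, and Mt2 and Mt1 12.00 and 9.99. Of 22 immediate early genes 9 rose, and 20 when adjusted over the list alone (median 4.06, camera adjusted p = 4.9e-11, and adjusted p = 0.330 with an estimated correlation), among them Gadd45b at 6.20, Junb at 4.15 and Klf10 at 3.35. Of 16 lipid droplet genes 4 rose, and 10 when adjusted over the list alone (camera adjusted p = 1.4e-04, and adjusted p = 0.269 with an estimated correlation). They include Cidec, which enlarges droplets, at 6.78, Lpin1 at 3.54 and Plin5, a droplet coat protein, at 2.49. Igfbp1, a fasting hormone carrier, went from 422 ± 321 to 6640 ± 3162 CPM and Tat, which breaks down tyrosine, from 1361 to 5761 CPM, log2 changes of 4.59 and 2.69. Syt12, Ly6d and Dusp8 rose by 8.38, 6.21 and 6.19. The largest falls were of Clec2h, from 78.8 ± 56.1 to 0.799 CPM (log2 change −6.00, SE 0.74, adjusted p = 0.0204), and Gas1, a growth arrest gene, at −5.81. Onecut1, a transcription factor of hepatocyte identity, went from 189 to 17.6 CPM (−2.94), and Fam13a, Fbxo21, Arrdc3, Pde9a, Zfp467, Tnfaip2 and Fmn1 changed by −4.38, −3.86, −3.23, −3.19, −3.06, −3.00 and −2.95. edgeR called 362 genes higher and 351 lower (713 in all, 3975 before adjustment), and DESeq2 called 2909. Pools differ here too, and edgeR called 0 genes without ChATflox sham, ChATflox;Mb1-Cre sham or ChATflox;Mb1-Cre 4 h, as labelled (2750, 1401 and 1867 before adjustment), and 4 without ChATflox 4 h. It called 402 and 408 without ChATflox 2 h and ChATflox;Mb1-Cre 2 h, 2674 and 2521 without ChATflox 24 h and ChATflox;Mb1-Cre 24 h, and 347 when cells were thinned to at most 2000 UMIs each.

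Directly between 2 h and 4 h, within 1 pool, edgeR called 0 genes in hepatocyte-like cells (919 before adjustment), and DESeq2 called 144, so which genes came on between these times was not resolved. This comparison was added after the data were seen.

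At 24 h, compared with sham inside 1 pool, Lcn2 and Saa1 were among the genes that had risen in hepatocyte-like cells, and the metabolic enzyme genes Hsd3b5 and Sult2a8 among those that had fallen. Hsd3b5, a steroid dehydrogenase typical of male mouse liver (chromosome 3, 98618634 to 98630252), went from 92.2 ± 17.3 to 0.691 CPM (SD, n = 2), a log2 change of −7.13 (SE 0.64, adjusted p = 0.0268). Sult2a8, a bile acid sulfotransferase, went from 942 ± 214 to 44.3 ± 6.35 CPM (log2 change −4.45, SE 0.36, adjusted p = 0.0233), and Aqp8, a water channel, from 396 to 25.5 CPM (−4.09). Serpina6, which carries corticosteroids in blood, changed by −3.35, the receptor gene Lifr by −2.91, Nudt7, a peroxisomal hydrolase of coenzyme A, by −3.29, and Afmid, an enzyme of tryptophan breakdown, by −3.59. Clec2h, Abca8a, Neb and Tlcd2 changed by −6.83, −3.97, −3.38 and −3.15. Of 18 genes of the type I interferon response 1 fell, and 13 when adjusted over the list alone (median −1.61, camera adjusted p = 2.7e-09, and adjusted p = 0.258 with an estimated correlation), among them Ifit3 at −3.57. Of 24 genes of the interferon-gamma response 2 fell, and 11 when adjusted over the list alone (median −1.62, camera adjusted p = 2.5e-09, and adjusted p = 0.162 with an estimated correlation), with Gbp7, a guanylate-binding protein, at −2.16 and Psmb8, an immunoproteasome subunit, at −1.46. A hepatocyte-like cluster whose second best name was Kupffer cell (30.8% doublets) held 246 and 263 cells of the libraries labelled ChATflox sham and ChATflox;Mb1-Cre sham, and 0 at 24 h. A cluster of both kinds of marker left out for its doublets (48.2%) held 0 sham cells, and 189 and 21 in the ChATflox and ChATflox;Mb1-Cre livers at 24 h. How much this adds to the falls of the interferon lists was not tested. Of 20 genes of cholesterol synthesis 0 were called by edgeR, and 7 fell when adjusted over the list alone (median −1.25, camera adjusted p = 1.3e-05, and adjusted p = 0.399 with an estimated correlation). Of 15 pericentral zone genes, which mark hepatocytes near the central vein, 0 were called, and 4 fell when adjusted over the list alone (median −1.20, camera adjusted p = 2.0e-05, and adjusted p = 0.258 with an estimated correlation). Lcn2 went from 4.70 ± 0.679 to 4482 ± 461 CPM (log2 change 9.82, SE 0.68, adjusted p = 0.0233), Saa2, Saa1 and Orm3, an acid glycoprotein, rose by 8.84, 7.35 and 5.04, and Mt2 and Mt1 by 9.44 and 8.14. The 2 livers at 24 h lay far apart in Mt2 and Mt1 (2901 ± 2896 and 4073 ± 4330 CPM, SD, n = 2), with log2 changes of 10.40 and 9.25 without ChATflox 24 h and 8.05 and 6.49 without ChATflox;Mb1-Cre 24 h. Of the 26 acute phase genes 6 rose, and 17 when adjusted over the list alone (median 1.59, camera adjusted p = 1.9e-11, and adjusted p = 0.258 with an estimated correlation). Ly6d, Bmper, Syt12 and Fabp4, a fatty acid carrier, rose by 7.80, 7.75, 6.18 and 4.49, and Por, the reductase that feeds cytochromes P450, went from 170 to 819 CPM (2.17). edgeR called 36 genes higher and 57 lower (93 in all, 2577 before adjustment), and DESeq2 called 1332. edgeR called 0 genes without ChATflox sham or ChATflox;Mb1-Cre sham, as labelled (1592 and 860 before adjustment), 2 without either 2 h liver, 3 without either 4 h liver, 2429 without ChATflox 24 h and 35 without ChATflox;Mb1-Cre 24 h. The hepatocyte-like cells compared here come from different clusters, which are numbered from 0 in order of size. The largest was cluster 5 in both sham libraries (27.2% and 39.0% of these cells), 13 and 1 in the ChATflox and ChATflox;Mb1-Cre livers at 2 h (56.6% and 35.1%), 8 and 10 at 4 h (41.5% and 50.9%), and 4 and 11 at 24 h (65.6% and 54.1%). Hepatocyte-like cells with under 1% mitochondrial UMIs were 43.0% and 71.1% in the libraries labelled ChATflox sham and ChATflox;Mb1-Cre sham. In the same order they were 56.7% and 39.5% at 2 h, 25.7% and 44.0% at 4 h, and 81.1% and 63.1% at 24 h. In such cells alone 51 of 77 named hepatocyte calls were kept, and in the other cells 72.

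**Figure D2:**
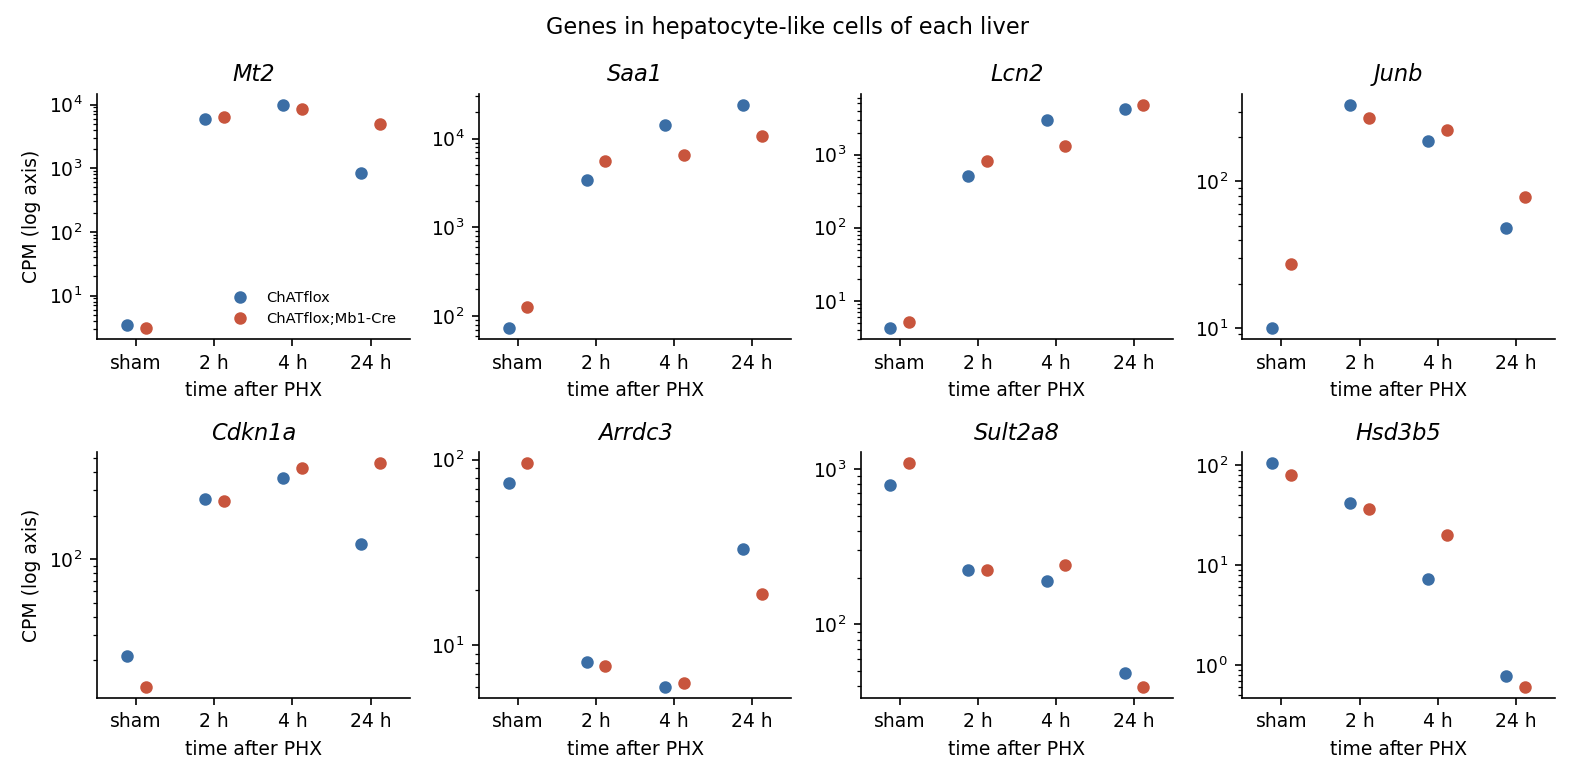
CPM (log axis) of 8 genes in the hepatocyte-like cells of each liver against time after PHX, each point 1 liver. Mt2 averaged 3.29 CPM in sham livers and 6166 CPM at 2 h, while Hsd3b5 averaged 92.2 CPM in sham livers and 0.691 CPM at 24 h.

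The genotype comparison fits 1 difference in hepatocytes, averaged over all 4 times. An effect at a single stage adds to the spread in this fit and can be missed. No gene passed in hepatocyte-like cells. The gene with the smallest p at a readable level was A1bg, a plasma glycoprotein, at a log2 ratio of ChATflox;Mb1-Cre to ChATflox of −2.42 (SE 0.45, adjusted p = 0.706). Tinag, with 2 and 55 UMIs in the same order, and Dgki, a lipid kinase, with 36 and 1 UMIs, had the same adjusted p. Of 18 genes of the unfolded protein and integrated stress response, 0 were called and 2 were lower when adjusted over the list alone (median −0.43, camera adjusted p = 3.0e-05, and adjusted p = 0.788 with an estimated correlation). The PPAR-alpha and pericentral lists had medians of −0.43 and −0.52 (camera adjusted p = 0.00108 and 0.00142, and adjusted p = 0.788 with an estimated correlation for both). The immediate early list had a median of 0.94 (camera adjusted p = 0.0131, and adjusted p = 0.788 with an estimated correlation). Of the 10 genes tested that make or sense acetylcholine, 0 were called (median −0.08, camera adjusted p = 0.910). The sum of all cells, which needs no cell classes, gave no call either, with A1bg at −2.51, Capn11 at −4.35 and Crat, carnitine acetyltransferase, at −1.04 (adjusted p = 0.697). edgeR called 0 genes in hepatocyte-like cells (620 before adjustment, 3 by DESeq2) and 0 in all cells (627 before adjustment, 2 by DESeq2). Without the ChATflox;Mb1-Cre 2 h liver 1 hepatocyte gene was called, and with the livers after PHX alone 0 (300 before adjustment). Over all comparisons of hepatocyte-like cells, camera with its preset correlation made 54 list calls, none of which held with an estimated correlation.

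Within single times, where 1 liver stands against 1 and no test was run, the genotypes lay far apart at 4 h and 24 h. More than 2-fold apart were 2.83% of hepatocyte genes in the sham pair, 4.75% at 2 h, 11.1% at 4 h and 27.1% at 24 h. At 24 h Cyp8b1, the enzyme that makes cholic acid, stood at 1.01 CPM in the ChATflox;Mb1-Cre liver and 414 CPM in the ChATflox liver, a ratio of 0.00245 (counting interval 0.00209 to 0.00285). Lgr5, a Wnt target of pericentral hepatocytes, stood at a ratio of 0.00336 (0.00153 to 0.00639), and Ivl, a structural protein of keratinised cells, gave 2311 UMIs against 0. At 4 h Ivl, Sprr1a, a related envelope protein, and Fosl1, an AP-1 subunit, had ratios of 214 (82.9 to 787), 168 and 121 (86.6 to 176), and Capn11 and Fam214a ratios of 0.0361 and 0.0475. At 2 h Fmr1nb, A2m, a protease inhibitor of plasma, and Reg3b, a secreted lectin, had ratios of 17.1, 8.65 and 6.33, and Ttyh1 and the interferon-induced chemokine Cxcl10 ratios of 0.0165 and 0.0206. In the sham pair as labelled, Ppp1r3g, a glycogen regulator, Fst, which binds activin, and Gadd45g had ratios of 8.49 (6.78 to 10.7), 7.39 and 7.24. Cyp2a22, Cabyr and the fasting hormone gene Fgf21 had ratios of 0.0641, 0.190 and 0.208. A contrast of the genotypes at 4 h and 24 h alone was added after these values, and the calls of 32 splits of the 8 livers into 2 groups of 4, were seen. Its hepatocyte count was the highest of those splits, a choice that its p-values do not allow for. It was fitted over all 8 livers with no genotype difference allowed in the sham and 2 h pairs, which then count as spread between livers. Each genotype still had 1 mouse at each time. This contrast called 150 hepatocyte genes with edgeR, 91 higher and 59 lower in ChATflox;Mb1-Cre (3143 before adjustment). In cells with few mitochondrial UMIs it called 820 and in the other cells 89, with 132 and 77 of the 150 called again. Its examples were chosen after their values were seen. Krt8, a keratin that hepatocytes raise under stress, stood at 379 and 287 CPM in the ChATflox livers at 4 h and 24 h and at 2217 and 2303 CPM in the ChATflox;Mb1-Cre livers (log2 ratio 2.55, SE 0.35, adjusted p = 0.0411). Nid1, a basement membrane protein, had a log2 ratio of 4.08 (SE 0.38, adjusted p = 0.0284), Hmox1, heme oxygenase, 2.77, and Leap2, a liver peptide that opposes ghrelin, −2.41. At sham, as labelled, and 2 h the Krt8 ratios were 0.907 and 0.583. The median log2 ratio of the 91 higher genes, without TMM factors, was 0.17 in the sham pair, −0.09 at 2 h, 1.5 at 4 h and 2.14 at 24 h. These genes were picked for a difference at 4 h and 24 h alone, so the choice itself favours this pattern. Genes picked as over 2-fold higher at 1 of these times had smaller medians at the other, with TMM factors. They were 0.958 at 24 h for genes picked at 4 h and 0.458 at 4 h for genes picked at 24 h.

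**Figure D3:**
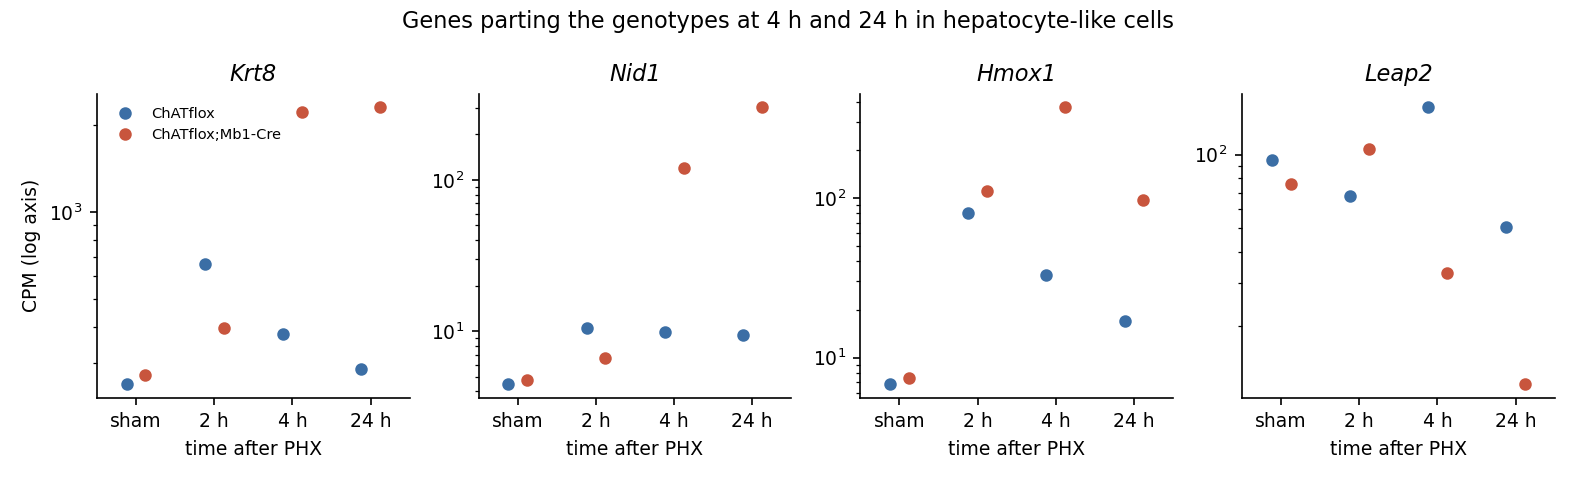
CPM (log axis) of Krt8, Nid1, Hmox1 and Leap2 in the hepatocyte-like cells of each liver against time after PHX, each point 1 liver. Krt8 lies at 2217 and 2303 CPM in the ChATflox;Mb1-Cre livers at 4 h and 24 h and at 379 and 287 CPM in the ChATflox livers.

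The other cells of the liver changed after PHX as well. Stellate cell-like cells, which store vitamin A and make matrix, had the most calls, with 444 genes higher and 176 lower at 2 h, 818 and 667 at 4 h, and 567 and 673 at 24 h. Of these, the genes with over 2 times their level in hepatocyte-like cells were 271 and 83, 469 and 138, and 453 and 35 in the same order. In them Adra2b, an adrenergic receptor gene, went from 131 to 3.32 CPM at 2 h (log2 change −5.20, SE 0.38, adjusted p = 0.00191). Sphk1, which makes the lipid mediator sphingosine 1-phosphate, changed by 7.28, 7.44 and 6.23 at the 3 times, Gas1 by −3.67, −5.46 and −3.28, and Nr1h5, a nuclear receptor gene, by −4.09 at 4 h. Gpx3, a secreted glutathione peroxidase, went from 4.96 to 590 ± 59.1 CPM at 24 h (SD, n = 2, log2 change 6.77, SE 0.36, adjusted p = 3.83e-04). Their immediate early genes were called higher in 17 of 22 at 2 h, and in 21 when adjusted over the list alone (median 3.32, camera adjusted p = 1.4e-16, and adjusted p = 0.440 with an estimated correlation). Ribosome biogenesis genes were higher in 12 of 18 at 2 h, and in all 18 when adjusted over the list alone (median 1.44, camera adjusted p = 2.0e-10, and adjusted p = 0.440 with an estimated correlation). In Kupffer cell-like cells, the resident macrophages, 5, 13 and 9 of 24 interferon-gamma response genes fell at 2 h, 4 h and 24 h, and 11, 17 and 20 when adjusted over the list alone. The medians were −0.77, −1.45 and −1.61 (camera adjusted p = 9.2e-09, 2.6e-10 and 3.2e-15, and adjusted p = 0.292, 0.209 and 0.125 with an estimated correlation). Ciita, the master switch of antigen presentation genes, went from 115 to 6.70 CPM at 2 h (log2 change −3.99, SE 0.34, adjusted p = 0.00470) and changed by −5.01 and −3.65 at 4 h and 24 h. The chemokine Cxcl9 and the GTPase Gbp2b changed by −3.80 and −3.69 at 24 h. Lepr, the leptin receptor gene, rose by 6.12, 6.52 and 5.63 in Kupffer cell-like cells at the 3 times. Tgfb3, a growth factor, rose by 6.60 at 2 h, Ddit4, a brake on mTOR, and Ms4a4a by 5.75 and 5.03 at 24 h, and Trem1, an activating receptor, gave 122 UMIs at 2 h against 0 in sham. Trem1 is also on the list of neutrophil markers, and neutrophil-like cells were more frequent at 2 h than in sham. Neutrophil RNA as its source was not tested. Tmem229a changed by −3.69 and −4.50 at 2 h and 4 h and Kcnj10, a potassium channel gene, by −3.11 at 2 h. In sinusoidal endothelial cell-like cells Rasd1, a glucocorticoid-induced GTPase, rose by 6.65, 6.23 and 5.99, Map3k6, a stress kinase, by 6.56 at 2 h and 6.06 at 24 h, and Gprc5b, an orphan receptor gene, by 6.67 at 4 h. Tiam1, an activator of Rac, changed by −3.69 and −5.18 at 4 h and 24 h, and Rab3il1 by −3.97 at 2 h. In T cell-like cells Ctla4, an inhibitory receptor gene, rose by 3.09 at 24 h, to 158 ± 164 CPM from 13.6, and Gzmk, a granzyme, stood at 27.1 CPM at 4 h against 1.09 CPM from 2 UMIs in sham. Lcn2, Saa1 and Saa2 were called higher in all 11 classes tested at 4 h and 24 h, and Mt1, Mt2 and Cxcl1 in all at 2 h. At 4 h Cdkn1a, Mt1, Mt2, Serpina3m and Steap4 were also called higher in all 11. Free RNA from hepatocytes was not examined for Cdkn1a, Cxcl1, Serpina3m and Steap4. Apart from the genes called in all classes, genes of the 10 other classes are named here only where their level was over 2 times that in hepatocyte-like cells, a limit set after values were seen. Such genes were 62.7%, 49.5% and 39.6% of the 1634, 4297 and 2392 calls at 2 h, 4 h and 24 h. Among all genes tested they ranged from 2135 of 9637 in cholangiocyte-like cells to 2176 of 3735 in NK cell or type 1 innate lymphoid cell-like cells. Of all 8323 calls 5016 were higher, and DESeq2 called 13194. Pools differ at 2 h and 4 h, and edgeR called 1911 and 343 genes without ChATflox sham and ChATflox;Mb1-Cre sham, as labelled, 3745 and 3191 without ChATflox 4 h and ChATflox;Mb1-Cre 4 h, and 27004 and 17488 without ChATflox 24 h and ChATflox;Mb1-Cre 24 h. These classes also came from different clusters at different times, as in Kupffer cell-like cells, where the largest was cluster 24 in sham, 7 at 2 h and 4 h, and 35 and 26 in the ChATflox and ChATflox;Mb1-Cre livers at 24 h, with stellate cell-like cells in 20, 2, 40 and 33 and sinusoidal endothelial cell-like cells in 0 in sham, 6 at 2 h, 3 at 4 h, and 12 and 9 at 24 h.

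**Figure D4:**
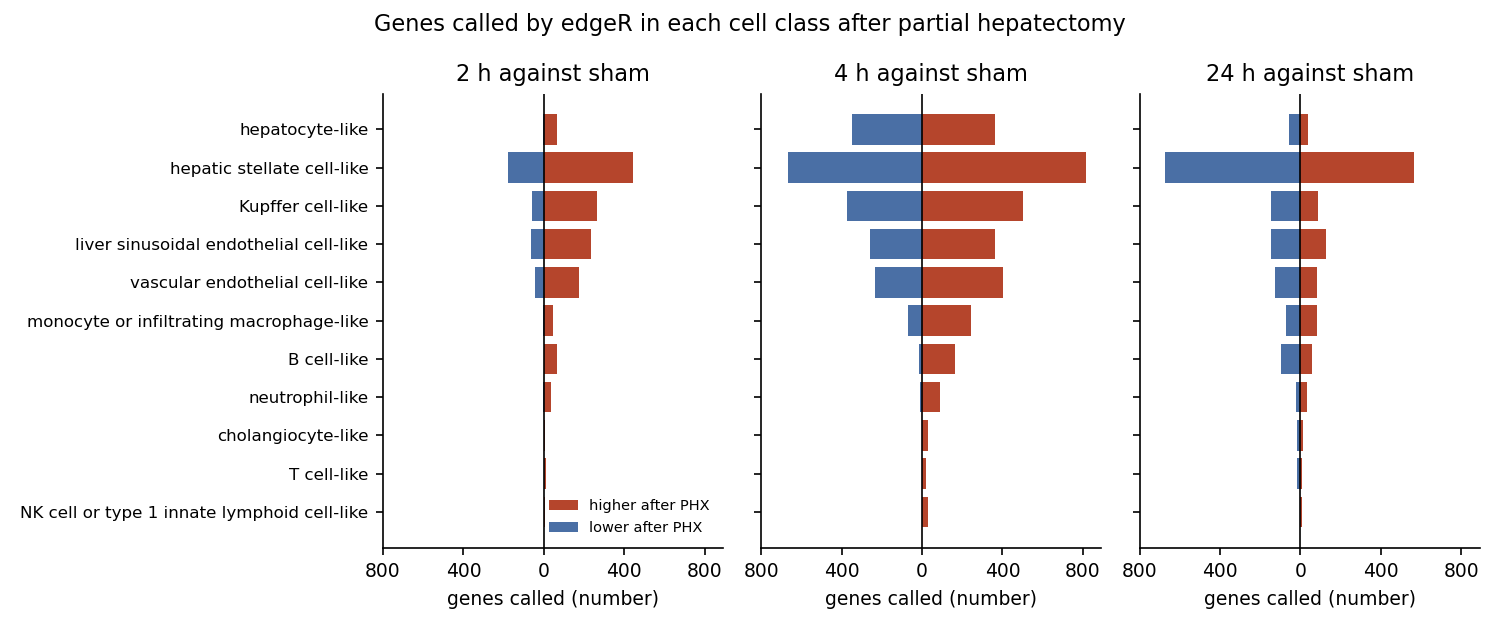
Number of genes edgeR called higher (right of 0) and lower (left of 0) than sham in each cell class at 2 h, 4 h and 24 h after PHX. Stellate cell-like cells had the most, 818 higher and 667 lower at 4 h.

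Between genotypes, the 10 other classes gave 1 call. Igfbp5, a secreted binding protein of insulin-like growth factors, was lower in vascular endothelial cell-like cells of ChATflox;Mb1-Cre livers, 18.3 ± 19.3 against 209 ± 208 CPM (SD, n = 4, log2 ratio −3.59, SE 0.40, adjusted p = 0.00653), and lower at 4 of 4 times, the sham pair as labelled included. Its counts were 19 and 222 UMIs. In neutrophil-like cells Scara5, a ferritin receptor gene, stood at −3.09 (adjusted p = 0.0509), and Apoa4, an apolipoprotein, and Aldh1b1, a mitochondrial dehydrogenase, at −2.11 and −3.69 (adjusted p = 0.080). In Kupffer cell-like cells Agpat2, an enzyme of lipid synthesis, and Dnajc22 stood at −0.77 and −0.89, and Acot5, a thioesterase, gave 0 UMIs in ChATflox (adjusted p = 0.538 for the 3). In T cell-like cells Ppp1r3b, a glycogen regulator, stood at −1.83, Ctla4 at 1.66 and Igkc, an antibody light chain, at 2.39 (adjusted p = 0.933). edgeR called 0 genes in Kupffer cell-like cells (1001 before adjustment, 1 by DESeq2) and 0 in T cell-like cells (407 before adjustment, 0 by DESeq2), and DESeq2 called 56 genes over the 10 classes, Igfbp5 among them and 50 of them in neutrophil-like cells. The Igfbp5 call ended without the ChATflox;Mb1-Cre 2 h liver (adjusted p = 0.0874), with the minimum depth per cell doubled (0.0515) and without time in the model (0.999), and held under the other alternatives run, at 2.7e-14 with no count filter to 0.0471 without ChATflox 2 h. With the 2 sham labels exchanged, a split run after the results were seen, edgeR called 0 genes in vascular endothelial cell-like cells (799 before adjustment, no other tool run). Over the 10 classes edgeR called 5 genes without either sham library, 132 and 138 without ChATflox 2 h and ChATflox;Mb1-Cre 2 h (121 and 128 of them in neutrophil-like cells), 3 without either 4 h liver, and 22 and 19 without ChATflox 24 h and ChATflox;Mb1-Cre 24 h.

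The make-up of the livers was compared as shares of cells. Neutrophil-like cells, which enter injured tissue first, were 0.335% and 0.420% of cells in the libraries labelled ChATflox sham and ChATflox;Mb1-Cre sham. They were 3.15% and 2.79% at 2 h, 2.15% in both livers at 4 h, and 0.608% and 3.05% at 24 h (57 and 309 cells). B cell-like cells were 2.07% and 3.87% in the same order in sham, 0.788% and 0.917% at 2 h, 0.413% and 0.254% at 4 h, and 0.480% and 0.858% at 24 h. Monocyte or infiltrating macrophage-like cells ranged from 0.341% in the ChATflox 24 h liver to 1.98% in the ChATflox 2 h liver. Kupffer cell-like cells were 9.03% to 11.1% of the cells of 7 livers and 14.6% in the ChATflox;Mb1-Cre 24 h liver. Plasma cell-like cells were more frequent in ChATflox;Mb1-Cre at 4 of 4 times, the sham pair as labelled, by a mean of 0.0214 percentage points (SD 0.00468, exact sign-flip p = 0.125, adjusted p = 0.865 over the classes). With the 2 sham labels exchanged they were more frequent at 3 of 4 times, by a mean of 0.00811 (SD 0.0233, exact sign-flip p = 0.625). Plasma cell-like cells numbered as few as 3 and 5, at 2 h. As a share of non-hepatocyte cells the 24 h pair ran the other way, with 0.363% in ChATflox and 0.332% in ChATflox;Mb1-Cre (mean 0.0277 percentage points over the 4 pairs, SD 0.0415, exact sign-flip p = 0.375). The mean genotype difference was 0.535 percentage points for B cell-like cells (SD 0.867, exact sign-flip p = 0.375) and 0.539 for neutrophil-like cells (SD 1.28, exact sign-flip p = 0.75), neither below an adjusted p = 0.865 over the classes. Without the sham pair the B cell-like difference was 0.116 and with its labels exchanged −0.362 (exact sign-flip p = 0.75 for both), and without the 24 h pair the neutrophil-like difference was −0.0943 (exact sign-flip p = 0.75). With 4 pairs this two-sided test cannot go below 0.125. Shares over time were not tested, with 2 livers per time, and depend on how cells survive preparation.

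**Figure D5:**
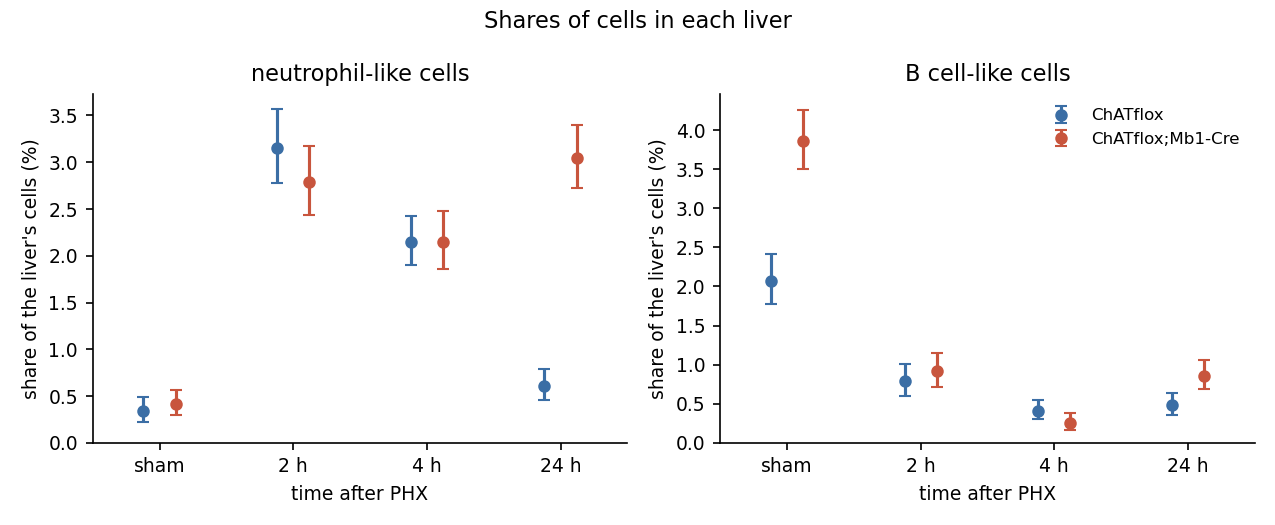
Share of each liver's cells (%) that were neutrophil-like or B cell-like against time after PHX, with exact 95% binomial intervals as bars. Neutrophil-like cells lie at 0.335% and 0.420% in the sham libraries and at 3.15% and 2.79% at 2 h.

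Division of hepatocytes is the usual readout of regeneration. Among cells with at least 2000 UMIs, thinned to that number, those with at least 2 UMIs of G2/M and mitosis genes numbered 1 to 8 per liver. They were 0.0864% and 0.0971% of these cells in the libraries labelled ChATflox sham and ChATflox;Mb1-Cre sham, and 0.0640% and 0.187% (0.0807% to 0.368%) in the ChATflox and ChATflox;Mb1-Cre livers at 24 h. The genotypes differed by a mean of 0.0201 percentage points (SD 0.0753, exact sign-flip p = 0.625), with ChATflox;Mb1-Cre higher at 3 of 4 times. With at least 1 UMI the difference was 0.168 percentage points. Unthinned cells with at least 2 UMIs gave −0.469 percentage points (SD 1.99, exact sign-flip p = 0.625), with ChATflox;Mb1-Cre higher at 1 of 4 times. Of 16 G2/M and mitosis genes tested at 24 h, 0 were called against sham, none also when adjusted over the list alone (median 0.38, camera adjusted p = 0.403, and adjusted p = 0.692 with an estimated correlation). Cells with at least 2 UMIs of G1/S and DNA replication genes were more frequent in ChATflox;Mb1-Cre at 4 of 4 times, the sham pair as labelled, with 8.06% against 4.53% at 24 h. The mean difference was 1.68 percentage points (SD 1.37, exact sign-flip p = 0.125). In unthinned cells it was −2.76 percentage points (SD 9.72, exact sign-flip p = 0.75), with ChATflox;Mb1-Cre higher at 2 of 4 times. With the 2 sham labels exchanged the difference in thinned cells was 0.736 percentage points (SD 2.22, exact sign-flip p = 0.625), higher at 3 of 4 times.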

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

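The tests of explanations, the splits of the livers and the test of a further genotype effect at 4 h and 24 h were chosen only after the results were seen, apart from the planned filter for at least 2 B cell markers. Of 46 groups of 4 livers searched for a liver far from the rest, 2 held one, and chance marks about 1 in 20 such groups. Both are the library labelled ChATflox;Mb1-Cre sham. For Chat, with 4 UMIs in its B cell-like cells against 0, the library is not shown to stand apart, since at their depth 0 allows 11.6 to 29.3 CPM in the other ChATflox;Mb1-Cre livers and this library gave 5.71 CPM.

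In that library, B cell-like cells gave 1.45 Cd79a UMIs per Cd79b UMI against 0.443 to 0.559 in the other ChATflox;Mb1-Cre livers, and the ratio of the sham pair, 2.10, lay on the other side of 1 from the 3 pairs after PHX, a difference that was not tested. Turned round, it is 0.475, inside the bounds of those pairs (0.181 to 0.771), so an exchange of the 2 sham labels is a candidate explanation. A wrong label on 1 sham library alone is argued against by the upper bound of the library labelled ChATflox sham, 0.801, below the lowest ChATflox liver after PHX (1.12), and free RNA by T cell-like cells, where Cd79a or Cd79b reach at most 2.02% of the B cell-like level and 42.8% would be needed. Other cells in the class stay open, since the planned filter for at least 2 B cell markers, with a ratio of 2.11, kept 167 of 167 and 384 of 387 cells and so decides nothing. B cells of sham livers may instead differ from those after PHX, which cannot be told apart with 1 sham pair.

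The genotypes parted in the same hepatocyte genes at 4 h and 24 h, with 150 called. An exchange of labels at these times is argued against by the Cd79a ratio only if the Cre allele lowers Cd79a. The highest upper bound of that ratio there is 0.481 against Cd79b and 0.667 against the other B cell markers. Whether the allele lowers it was not checked, since the probe positions are not given and the sham pair as labelled runs the other way. An effect of the probe barcodes is argued against only if the key holds, in which they cross between genotypes at the 2 times. The barcode and the matrix of the ChATflox 24 h liver could not be checked. For this, genes with at least 50 UMIs in a liver at both times were picked as over 2-fold apart at 1 of them, with 1 CPM added. Of these, 587 of 703 (picked at 4 h) and 1551 of 2031 (picked at 24 h) kept that direction at the other time. Their median log2 ratio there was at least 0.33 (quartiles 0.02 to 0.72, though for genes lower at 24 h the upper quartile at 4 h is 0.01). A different mix of hepatocyte-like cells with few and many mitochondrial UMIs is argued against by the median within them, at least 1.73 against 1.79 in all, with 132 and 77 of the 150 genes called again among 820 and 89 calls in cells with few and with many. A deletion that acts from 4 h on may account for it, but 1 mouse per genotype and time cannot tell it from differences between single mice, and the direct test of a further effect at 4 h and 24 h called 0 hepatocyte genes (edgeR, 1679 before adjustment, no other tool run). Of 12 contrasts of 2 pairs of times 1, the one chosen here with 150 genes, called as many, the highest other called 0, and 12 are too few for a share under 0.05. It was also chosen after these counts were seen, so its rank among them is not a test.

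That same test of a further genotype effect at 4 h and 24 h called 429 genes in cholangiocyte-like cells, 67 in vascular endothelial cell-like cells, 33 in NK cell or type 1 innate lymphoid cell-like cells and 13 in neutrophil-like cells, on 2 residual degrees of freedom. It called 0 in the other 6 classes, B, T, Kupffer, stellate, sinusoidal endothelial and monocyte or infiltrating macrophage-like cells (edgeR, 533, 429, 961, 1421, 1916 and 542 before adjustment, no other tool run). In cholangiocyte-like cells the median level of the hepatocyte markers was 58.9% to 90.9% of the hepatocyte-like level, depending on the liver. How much free RNA from hepatocytes adds to these calls was not tested.

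Saa1, Saa2, Lcn2, Mt1 and Mt2 rose after PHX in many classes that are not hepatocytes. After PHX their levels in the 10 other classes had medians of 55.0%, 53.1%, 54.1%, 61.3% and 60.3% of the hepatocyte-like level. Free RNA from hepatocytes as the only source of Mt1 in sinusoidal endothelial cell-like cells is argued against, since Mt1 lay above the highest of 12 hepatocyte markers in all 6 livers after PHX, at 1.11 times it or more (131% against 47.7% in the ChATflox 2 h liver). For the classes together free RNA stays open, with 46, 44, 38, 44 and 45 of 60 cases of a class in a liver within the range of the markers there. So does expression by the classes themselves, with 11, 10, 12, 16 and 15 cases above that range and 3, 6, 10, 0 and 0 below it. Each gene lay outside it more often than a further marker would be expected to. Lcn2 in neutrophil-like, Mt1 in stellate cell-like and Mt2 in sinusoidal endothelial cell-like cells lay above it in 5 of 6 livers each. In cholangiocyte-like cells none of these genes did in any liver.

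The livers can be split into 2 groups of 4 that can be fitted beside time in 32 ways. In hepatocyte-like cells all 32 gave at least the real count of 0 (highest other 150), and in all cells 32 did (real 0, highest other 35), which a count of 0 fixes, so these splits say nothing about chance. In the other classes together 15 of 32 gave at least the real count of 1 (highest other 3015), and in vascular endothelial cell-like cells 7 of 32 (real 1, highest other 474). Chance is therefore not excluded for the 1 call in the other classes, that in vascular endothelial cell-like cells. The highest counts come from a split that sets the genotypes apart at 4 h and 24 h alone, and so point to a structure of the samples. Among the 8 splits that part all 4 pairs the highest others were 2, 1, 185 and 1 in the same order.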

How the results depend on the processing

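The runs on 1 kind of hepatocyte-like cell, on the genotype effect at 4 h and 24 h only and on shares with the sham labels exchanged were chosen after the data were seen, and the rest was planned. Of 128 gene results named, 113 were called. None of their 2078 values under alternatives reversed, and 93 of the called ones stayed called under every alternative other than leaving out a liver or keeping 1 kind of cell. The naming rule favours large changes with the same direction in both genotypes, and the alternatives use the same livers. Reversals were therefore unlikely from the start, and their absence is no independent check. DESeq2 kept 113, thinning 96, and leaving out the libraries labelled ChATflox sham and ChATflox;Mb1-Cre sham 5 and 2. Counts moved more. DESeq2 called 1195, 2909 and 1332 genes in hepatocyte-like cells at 2 h, 4 h and 24 h (69, 713 and 93 by edgeR), 13194 by time in the other classes (8323), and between genotypes 3 in hepatocyte-like cells, 56 in the other classes and 2 in all cells (0, 1 and 0). Without a count filter 136 genes were called at 2 h, 15319 by time in the other classes and 231 between genotypes there. Without the genotype term 156, 1222 and 231 were called at 2 h, 4 h and 24 h. Thinned cells gave 347 and 49 at 4 h and 24 h, and cells with few mitochondrial UMIs 44, 391 and 19 at the 3 times. Doublets kept gave 14148 and the doubled resolution 13278 by time in the other classes. Between genotypes in the other classes, the fit with no replicate block of time and the doubled minimum of UMIs called 0 (edgeR, 2628 and 4565 before adjustment), and livers after PHX only 2. With no replicate block of time hepatocyte-like cells gave 0 (315 before adjustment). The effect at 4 h and 24 h only called 150 genes in hepatocyte-like cells, 3015 in the other classes and 35 in all cells. Leaving out 1 liver at a time gave 0 to 411, 0 to 2674 and 0 to 2429 genes in hepatocyte-like cells at 2 h, 4 h and 24 h, 343 to 27004 by time in the other classes, and between genotypes 0 to 1, 3 to 138 and 0 to 0 in hepatocyte-like cells, the other classes and all cells. A lone liver left at a time is assumed to vary like the others, and fewer livers leave fewer residual degrees of freedom. Of 54 list calls in hepatocyte-like cells, the estimated correlation left 0 and fry made 26. Of 125 shares of cells under alternatives 118 lay within 1 SD of the reported genotype difference. The others were, in percentage points of non-hepatocyte cells, stellate cell-like −1.10, sinusoidal endothelial cell-like −2.20 and plasma cell-like 0.0277, plasma cell-like 0.0331 with the doubled minimum of UMIs and 0.0166 with the doubled resolution, and B cell-like −0.362 and plasma cell-like 0.00811 with the sham labels exchanged. For cycling hepatocyte-like cells the difference of 0.0201 points became 0.168 with at least 1 UMI, −0.469 in unthinned cells 1.68 with the G1/S list, and with the sham labels exchanged 0.0148 (0.736 with the G1/S list). The cause of these changes was not tested. Pool as a further term was not run, since it cannot be estimated beside time. Depth limits Chat, with 0 UMIs in the B cell-like cells of 7 livers, and in simulated counts 5% of 2-fold changes were recovered in hepatocyte-like cells at 24 h against sham.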

Other observations

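The shares of cycling Kupffer cell-like cells, the genotype contrast at 4 h and 24 h and the genes named from it were chosen after the data were seen, and the gene lists were planned. Kupffer cells renew by dividing in place. Of 19 G2/M and mitosis genes 4 fell in Kupffer cell-like cells at 24 h, and 16 when adjusted over the list alone (median −1.67, camera adjusted p = 4.0e-11, and adjusted p = 0.360 with an estimated correlation). Among cells with at least 1000 UMIs, thinned to that number, those with at least 2 UMIs of this list were 4.29% (2.91% to 6.07%) and 4.26% (3.03% to 5.80%) of Kupffer cell-like cells in the libraries labelled ChATflox sham and ChATflox;Mb1-Cre sham. They were 2.79% and 3.63% in the ChATflox and ChATflox;Mb1-Cre livers at 2 h, 5.62% and 3.86% at 4 h, and 1.37% (0.708% to 2.38%) and 2.18% (1.48% to 3.10%) at 24 h. Genes of the type I interferon response fell beside them in Kupffer cell-like cells, 10 of 18 at 24 h and 17 when adjusted over the list alone (median −1.64, camera adjusted p = 1.9e-14, and adjusted p = 0.260 with an estimated correlation). In sinusoidal endothelial cell-like cells 5 of 18 fell at 24 h, and 14 when adjusted over the list alone (median −1.39, camera adjusted p = 4.5e-10, and adjusted p = 0.460 with an estimated correlation). There 5 of 23 angiocrine and regeneration factors, the signals by which endothelium instructs hepatocytes, rose at 24 h, with 8 higher and 3 lower when adjusted over the list alone (median 0.49, camera adjusted p = 0.236, and adjusted p = 0.472 with an estimated correlation).

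The genotype contrast at 4 h and 24 h was also run in the 10 other classes. edgeR called 913 genes in sinusoidal endothelial cell-like cells (452 higher and 461 lower in ChATflox;Mb1-Cre), 605 in neutrophil-like, 474 in vascular endothelial cell-like, 359 in cholangiocyte-like, 329 in stellate cell-like and 143 in NK cell or type 1 innate lymphoid cell-like cells. It called 92 in Kupffer cell-like, 75 in monocyte or infiltrating macrophage-like and 25 in B cell-like cells, and 0 in T cell-like cells (827 before adjustment, no other tool run). The called genes whose level was over 2 times that in hepatocyte-like cells were 48.5%, 29.8%, 33.8%, 29.8%, 41.9%, 24.5%, 32.6%, 16% and 16% of these 9 counts in the same order. Among all genes tested there such genes were 5018 of 11412, 2022 of 6793, 3505 of 8176, 2135 of 9637, 3443 of 11204, 2176 of 3735, 4749 of 11239, 4070 of 8359 and 2311 of 5944. The called share lay below this in vascular endothelial, NK, Kupffer, monocyte and B cell-like cells. It lay above it in sinusoidal endothelial, cholangiocyte and stellate cell-like cells. In sinusoidal endothelial cell-like cells Adamts9, a matrix protease, stood at a log2 ratio of 2.43 (SE 0.27, adjusted p = 0.0113) and Actn1, an actin crosslinker, at 1.84 (SE 0.26, adjusted p = 0.0149). In hepatocyte-like cells the acute phase list was lower in ChATflox;Mb1-Cre, with 2 of 26 called and 11 lower and 1 higher when adjusted over the list alone (median −0.50, camera adjusted p = 3.3e-04, and adjusted p = 0.590 with an estimated correlation). The immediate early list was higher, with 2 of 22 called and 10 when adjusted over the list alone (median 1.97, camera adjusted p = 1.3e-04, and adjusted p = 0.635 with an estimated correlation).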
